A study of Mus musculus with 3 samples.

How the data were processed

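RNA of whole proximal jejunum (the upper part of the small intestine after the duodenum) from mice lacking Sox4 through villin-Cre, a recombinase expressed in the intestinal epithelium, was compared with RNA of wild-type proximal jejunum on 3 Agilent arrays with 2 colours. Per the labels, total RNA was prepared with an RNeasy kit, the knockout RNA carried Cy5 and the wild-type RNA Cy3 on every array, and each array held a different knockout mouse. No dye swap and no array of wild-type RNA alone was among the samples, and the labels do not say whether the wild-type RNA was a pool or came from individual mice. All 3 arrays therefore form 1 group, Sox4 knockout with replicates 1 to 3, each set against wild type within the array.

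The deposited values are log2 ratios of the 2 channels, 62976 numbered features on each of 3 arrays with no missing value. The authors' background correction, normalization and filters, the log base and the direction of the ratio are not given in the sources used here. Base 10 was excluded because ratios from -7.44 to 5.62 would exceed the range of a scanner, and base 2 was taken over the natural logarithm as the usual unit, which the values alone do not settle. Under the natural logarithm each fold given here would be larger. The ratios were read as knockout over wild type because the labels put the knockout in Cy5, and all signs would turn if the table held Cy3 over Cy5. The array medians were 0.007, 0.003 and 0.011, so the ratios had been centred or normalized within each array, and they were used without further scaling. No intensities were used here, so features near background could not be removed, and the number of arrays limits the precision.

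Features were named through the platform's annotation, updated by accession through a RefSeq gene table of mouse assembly GRCm38.p6, which served for names only. Of 31465 features with 1 gene symbol, 29036 were named by accession, 2075 by current symbol and 349 by synonym, and 5 kept an old symbol. No feature had several symbols, and 31511 features were unnamed here, which does not mean that they lack a gene. Features of 1 symbol were averaged on each array, giving 20738 genes, 6171 of them with more than 1 feature.

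The mean ratio of each gene was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept, then eBayes, 2 residual and 3.51 prior degrees of freedom). The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over all 20738 genes, and the threshold was an adjusted p of 0.05. Errors are SDs over the arrays, and intervals are 95% intervals of the moderated test. A ratio tested against 0 leaves out the spread between wild-type mice, and without a dye swap a gene-specific dye effect cannot be separated from genotype. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

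Before the data were examined, 40 gene lists were fixed: cell types of the intestinal epithelium, other cell types that whole jejunum can hold, signalling, epigenetic, metabolic, stress and immune pathways, reference genes and sex-linked genes. The 39 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over these lists. Camera was repeated with a correlation estimated for each list, and fry served as a further set test. Each list's members past the threshold were counted with p-values adjusted over all genes and adjusted over the list alone, and each array's list median was placed among 10000 random lists of the same size. The count over the list alone was not made for random lists. As 26.3% of all genes had an unadjusted p under 0.05, a list of unrelated genes can also hold such members.

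The rule for naming genes, also fixed then, took Sox4, the 10 largest rises and 10 largest falls among genes past the threshold with the same sign on all arrays (numbered and unnamed loci replaced by the next gene), and in each list up to 4 members with the smallest p. Genes given with values outside it and outside the tests of the closing section are marked as chosen after their values were seen.

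The scripts were tested on simulated data of 20738 genes on 3 arrays with the spread of the real ones. Of 50 genes changed at each size, 2% were called at a log2 size of 0.5, 32% at 1, 90% at 2 and 100% at 4, with 5 false calls. Unchanged genes were simulated without any ratio shared by the arrays, such as a dye effect would give. The 5 false calls therefore do not estimate how many there are among the real genes. Camera with the preset correlation called 5 of 5 lists shifted by 0.5, and with an estimated correlation it called 0 of them, so the latter had little power at this number of arrays. Neither called an unshifted list, but the simulated genes were drawn independently of each other. The run therefore does not show how often the preset correlation calls lists whose genes vary together. Estimated correlations were 0.81 for the tuft cell, 0.60 for the type 2, 0.55 for the proliferation and 0.52 for the MHC class II list.

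The alternatives were median centring, quantile normalization, scaling of each array to 1 median absolute log ratio (limma's normalizeMedianAbsValues), the median over a gene's features, 1 value per feature, robust variance moderation, array weights, leaving out 589 genes with an exact 0 or an extreme value on an array, leaving out each array, a minimum fold of 1.5, and an adjusted p of 0.10. Averaging within accessions before genes was added after seeing the data.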

Results

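Gene expression was measured in whole proximal jejunum of mice with Sox4 deleted in the intestinal epithelium, relative to wild-type jejunum, on 3 two-colour arrays with 1 knockout mouse each. The series asks how the transcription factor Sox4 acts on cell division, differentiation and DNA methylation in this epithelium. Ratios of 20738 genes were available on all 3 arrays, with standard deviations across genes of 0.47, 0.50 and 0.46 on arrays 1, 2 and 3. All values below are log2 ratios of knockout over wild type with the SD over n = 3 arrays.

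Sox4 itself had a mean of -0.31 ± 0.44 (95% interval -0.78 to 0.15, n = 3) and did not pass the threshold (adjusted p = 0.332). Its ratio was -0.66 on array 1, 0.18 on array 2 and -0.46 on array 3, so the library labelled Sox4 knockout on array 2 was not below wild type for the gene as a whole. The 3 Sox4 features disagreed. Feature 53932 was lower on every array, with ratios of -1.21, -0.72 and -0.93 (mean -0.95 ± 0.25), feature 35668 averaged -0.41 ± 0.43, and feature 32792 averaged 0.42 ± 0.70 with 1.23 on array 2. The positions of these features relative to the deleted part are not used here, and whole tissue holds cells in which villin-Cre is not active, so Sox4 is a weak check of the labels, most of all on array 2. Directions below rest on the labels, and for array 2 on a library labelled Sox4 knockout in which the mean of the Sox4 features did not lie below wild type.

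Of 20738 genes, 68 passed the threshold, 22 higher and 46 lower in the knockout, and each of them had the same sign on all 3 arrays. The largest fall was that of the Y-linked translation factor gene Eif2s3y, at -7.28 ± 0.25 (155-fold lower, adjusted p = 0.000252). The hormone genes Nts (neurotensin, -6.51 ± 0.32, 90.9-fold lower) and Gcg (proglucagon, -5.21 ± 0.14, 37.1-fold lower) and the adipocyte genes Cfd (adipsin, -5.95 ± 0.65) and Adipoq (adiponectin, -4.69 ± 0.41) followed. Car3, a carbonic anhydrase abundant in fat and muscle (-3.62 ± 0.50), the purine phosphorylase gene Pnp2 (-3.34 ± 0.25), the Y-linked genes Uty (-3.05 ± 0.91) and Ssty2 (-2.24 ± 0.31) and Scd1, a fatty acid desaturase (-2.16 ± 0.29), also fell.

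The largest rise was that of the organic anion transporter gene Slc22a7, at 3.83 ± 0.22 (14.3-fold higher, adjusted p = 0.00159). The metallothionein gene Mt1 rose by 2.82 ± 0.06 (7.08-fold, adjusted p = 0.00209). Prss38 (1.97 ± 0.11), the non-classical MHC gene H2-T3 (1.87 ± 0.22), the defensin gene Defb21 (1.80 ± 0.32), the olfactory receptor gene Olfr487 (1.75 ± 0.13) and Xist (1.71 ± 0.18), the RNA that coats the inactive X chromosome, also rose. Smaller rises were those of Lypd8 (1.52 ± 0.27), the butyrophilin-like gene Btnl4 (1.33 ± 0.06) and Rassf4 (1.30 ± 0.27). Of the 68 genes, 59 rested on 1 feature, and 26.3% of all genes had an unadjusted p under 0.05. With 2 arrays the count was 10 without array 1, 66 without array 2 and 4 without array 3, sharing 9, 25 and 4 genes with the 68, and only Eif2s3y, Nts, Gcg and Pnp2 passed whichever array was left out.

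**Figure D1:**
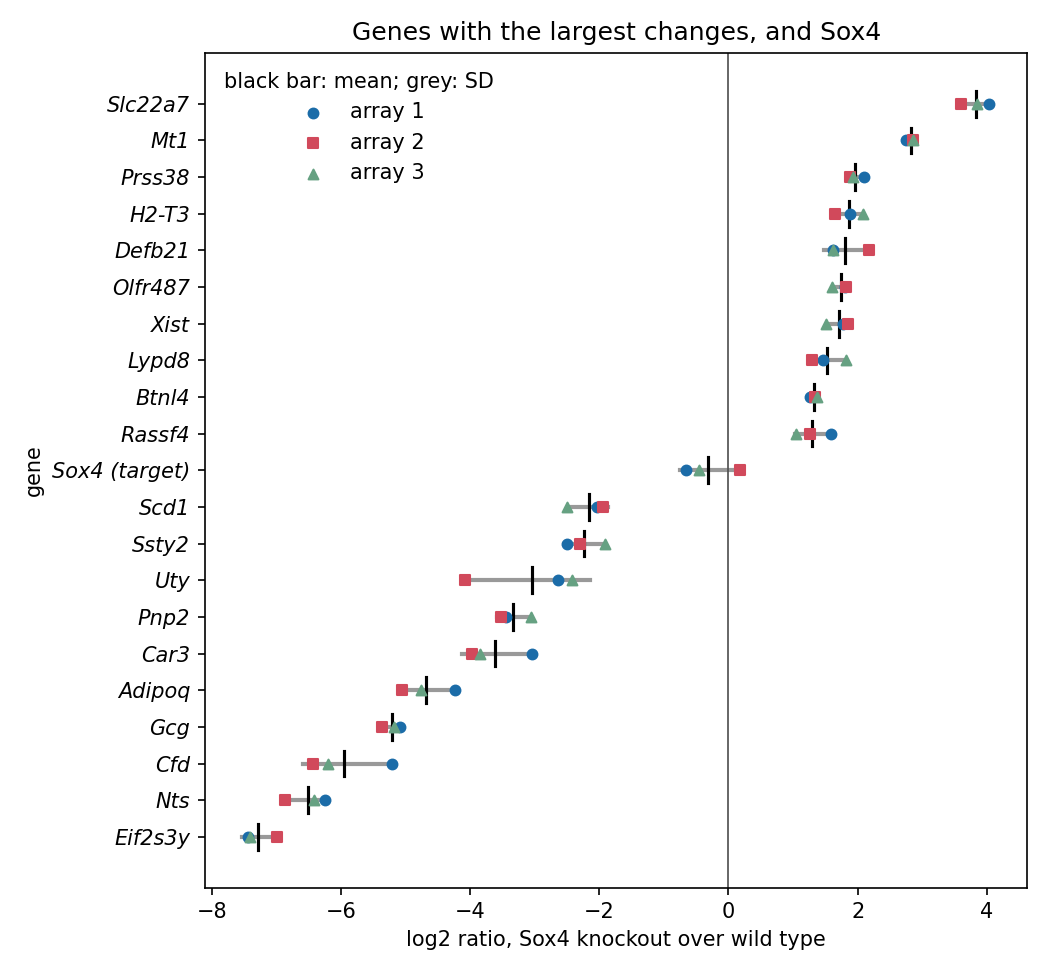
Log2 ratio of Sox4 knockout over wild-type jejunum (horizontal axis) for Sox4 and the 20 genes of the naming rule (vertical axis); points are the 3 arrays, black bars the means and grey lines the SD. The means run from -7.28 for Eif2s3y to 3.83 for Slc22a7, and Sox4 has arrays on both sides of 0.

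The sex-linked genes differed on every array. Eif2s3y and Uty fell and Xist rose (3.27-fold higher), while Kdm5d, also Y-linked, had -1.11 ± 0.41 (adjusted p = 0.0640) and passed only when adjusted over the list alone. With 4 measured members this list was not tested as a set. The sex of the mice is not stated in the labels used here. Every gene group below was measured in the same RNA, so an effect of sex could not be separated from one of genotype in any of them.

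Among enteroendocrine genes, which mark the hormone-secreting cells of the epithelium, 5 of 43 fell and none rose. Beside Nts and Gcg these were Cck (cholecystokinin, -1.82 ± 0.42), Pyy (peptide YY, -1.43 ± 0.20) and the granule protein gene Scg2 (-1.17 ± 0.17), the last chosen after its value was seen. Adjusted over the list alone, 18 members were lower and 2 higher. The list's median was -0.44 (camera adjusted p = 3.3e-07, and adjusted p = 0.837 with an estimated correlation), with array medians of -0.41, -0.81 and -0.23. Members did not move alike. The 2 higher over the list alone were Ghrl (ghrelin, 0.68 ± 0.10) and the transcription factor gene Neurog3 (0.45 ± 0.20), and Chgb (chromogranin B) had -0.00 ± 0.59. None of these genes passed over all genes, and all were chosen after their values were seen.

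The tuft cell list, marking the chemosensory cells of the epithelium, had a median of -0.23 over 36 genes (camera adjusted p = 0.0262, and adjusted p = 0.843 with an estimated correlation). None of its members passed over all genes, and 2 were lower adjusted over the list alone, Rgs13 (-2.40 ± 0.81) and Tuba1a (-0.70 ± 0.24). An unadjusted p under 0.05 was found for 7 of its 36 genes, all lower, a smaller share than the 26.3% of all genes. The signalling subunit gene Gng13 had -1.10 ± 0.78 and Il25, the tuft cell cytokine, -0.62 ± 0.45. Other members had means near 0, among them Dclk1 (-0.03 ± 0.64), Trpm5 (-0.08 ± 1.20) and Pou2f3 (0.17 ± 1.02), chosen after their values were seen. On array 2 these had 0.65, 1.21 and 1.34. In all, 30 of the 36 members had a mean below 0 and 6 above. The arrays differed in direction, with list medians of -0.96 on array 1, 0.37 on array 2 and -0.43 on array 3. On array 2 the mean of the Sox4 features was not below wild type, although feature 53932 was (-0.72). Leaving out array 1 moved the median to -0.02 (adjusted p = 0.695), leaving out array 3 to -0.17 (adjusted p = 0.205), and leaving out array 2 to -0.71.

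The type 2 immune response list had the same arrangement, with medians of -0.98, 0.09 and -0.56 on arrays 1, 2 and 3. Over its 18 genes the median was -0.60 (camera adjusted p = 0.0118, and adjusted p = 0.837 with an estimated correlation). No member passed over all genes, 8 had an unadjusted p under 0.05, and 3 were lower adjusted over the list alone, among them the chemokine gene Ccl24 (95% interval -1.33 to -0.67) and the cytokine genes Il9 (-0.68 ± 0.20) and Il33 (-0.60 ± 0.26), with Arg1 at -0.60 ± 0.42. The shift missed the threshold without array 1 (median -0.15, adjusted p = 0.241) and without array 3 (adjusted p = 0.0565). Il25 is also in the tuft cell list. The list of mast cell, eosinophil and neutrophil genes, which shares Mcpt1 and Mcpt2 with the type 2 list, had medians of -0.51, 0.09 and -0.26. It did not pass (camera adjusted p = 0.163), nor did any of its 22 members in either count. Of these members 7 had an unadjusted p under 0.05, where 26.3% of all genes had one. The mast cell gene Fcer1a had ratios of -4.20, -0.57 and -3.50 on arrays 1, 2 and 3, Ms4a2 had -3.98, -0.70 and -2.14, and Cpa3 had -3.99, 0.03 and -3.08. Without array 2, Fcer1a (adjusted p = 0.0251) and Cpa3 (adjusted p = 0.0342) passed over all genes.

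**Figure D2:**
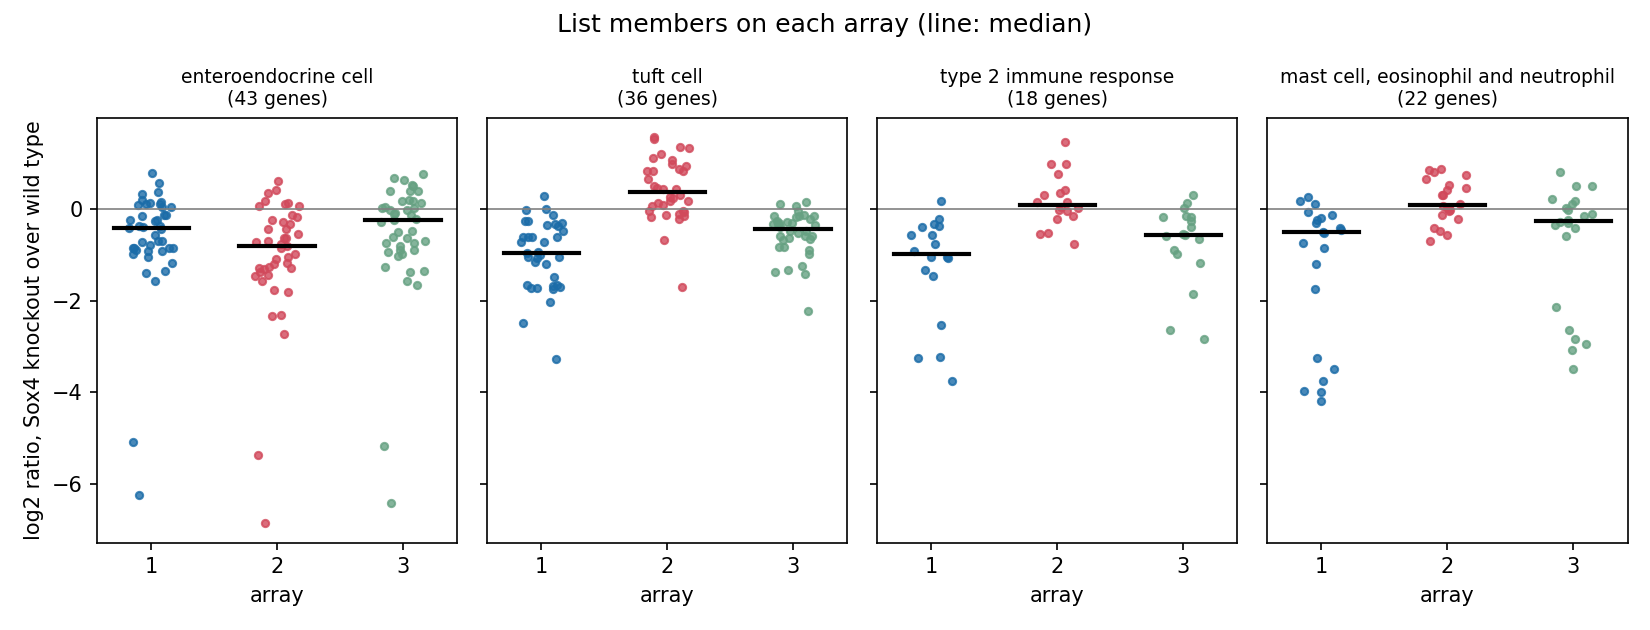
Log2 ratio of Sox4 knockout over wild type (vertical axis) of each member of 4 gene lists on arrays 1 to 3 (horizontal axis); points are genes and lines medians. The enteroendocrine medians lie below 0 on every array, whereas the tuft cell medians are -0.96, 0.37 and -0.43.

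Genes of xenobiotic and glutathione metabolism, which modify and export foreign compounds, were lower as a group. The median over 33 members was -0.65 (camera adjusted p = 2.1e-11, and adjusted p = 0.837 with an estimated correlation), between -0.61 and -0.76 on the 3 arrays. The cytochrome P450 genes Cyp2c55 (-1.78 ± 0.28, 3.43-fold lower) and Cyp3a25 (-1.08 ± 0.09) fell, and 25 members were lower adjusted over the list alone. The carboxylesterase gene Ces2a had -1.43 ± 0.41 and Cyp2c66 -0.87 ± 0.08, without passing over all genes.

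Of 14 genes of mesenteric fat, a tissue attached to the gut wall, 11 were below 0 on every array, and the list's median was -0.63 (camera adjusted p = 2.0e-07, and adjusted p = 0.837 with an estimated correlation). Adipoq, Cfd, Car3, the perilipin gene Plin1 (-2.12 ± 0.20, chosen after its value was seen) and Retn (resistin, -2.09 ± 0.02) fell, and 11 were lower adjusted over the list alone. Of the 9 erythroid genes of blood, Hbb-bt (-1.59 ± 0.39) and Hbb-bs (-1.23 ± 0.19) fell, and 6 were lower and 1 higher adjusted over the list alone. The erythroid median was -1.23 (camera adjusted p = 0.000988, and adjusted p = 0.837 with an estimated correlation), and Hbb-b2 and Hba-a1 had -1.29 ± 0.31 and -1.34 ± 0.46. The pancreatic acinar list had a median of -0.31 over 21 genes (camera adjusted p = 0.0199, and adjusted p = 0.837 with an estimated correlation). No acinar member passed over all genes, while 6 were lower and 1 higher adjusted over the list alone. The digestive enzyme genes Try5, Try4 and Pnlip had -1.72 ± 0.46, -1.65 ± 0.77 and -1.24 ± 0.44, and Sycn had -1.10 ± 0.40. In this list Zg16 is also a goblet gene, and Clps and Pnliprp2 also stand among the Paneth genes. The acinar median was -0.16 without array 1 (adjusted p = 0.0507) and -0.51 without array 2.

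Proliferation genes were higher as a group, with a median of 0.32 over 39 members (camera adjusted p = 1.1e-05, and adjusted p = 0.837 with an estimated correlation). No member passed over all genes, 19 had an unadjusted p under 0.05, and 15 were higher and 1 lower adjusted over the list alone. The mitotic genes Cenpf and Hmmr had 0.98 ± 0.21 and 0.70 ± 0.11, the cell cycle regulator gene Foxm1 0.59 ± 0.14 and the replication helicase gene Mcm5 0.54 ± 0.09. Replication genes did not all rise. Pcna, the 1 lower member, had -0.45 ± 0.20 and Mcm6 -0.33 ± 0.22, both chosen after their values were seen. In all, 6 of the 39 members had a mean below 0. The array medians were 0.45, 0.11 and 0.49. Members varied together (estimated correlation 0.55), and fry gave this list an unadjusted p of 0.131. Reference genes, described below, had array medians of 0.31, 0.13 and 0.28, also above 0 and lowest on array 2. A smaller rise of the same kind was thus found outside the proliferation list.

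The MHC class II list, whose genes present antigens to T cells, had a median of 0.50 over 11 genes (camera adjusted p = 0.00479, and adjusted p = 0.837 with an estimated correlation). No member passed over all genes, and 6 were higher adjusted over the list alone, among them Cd74 (2.83-fold higher, SD 0.51 on the log2 scale), H2-Eb1 (0.88 ± 0.25), H2-Eb2 (0.72 ± 0.15) and H2-DMa (0.63 ± 0.41). The list of T and innate lymphoid cells had a median of -0.23 over 20 genes (camera adjusted p = 0.0483, and adjusted p = 0.837 with an estimated correlation). None of these passed over all genes and 8 were lower adjusted over the list alone, among them the cytotoxic granule genes Gzma (-0.77 ± 0.09) and Gzmb (-0.51 ± 0.10), Ccl5 (-0.68 ± 0.14) and Cd8b1 (-0.64 ± 0.21). This shift missed the threshold without array 1 (adjusted p = 0.0594) and without array 3 (adjusted p = 0.116). Reference genes, often taken as constant, had a median of 0.24 over 13 genes (camera adjusted p = 0.0199, and adjusted p = 0.837 with an estimated correlation), with Polr2a at 0.67 ± 0.22, Pgk1 at 0.43 ± 0.11, Rplp0 at 0.44 ± 0.21 and Gapdh at 0.58 ± 0.48. No reference gene passed over all genes, 1 was higher adjusted over the list alone, and without array 1 the shift had an adjusted p of 0.0786.

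**Figure D3:**
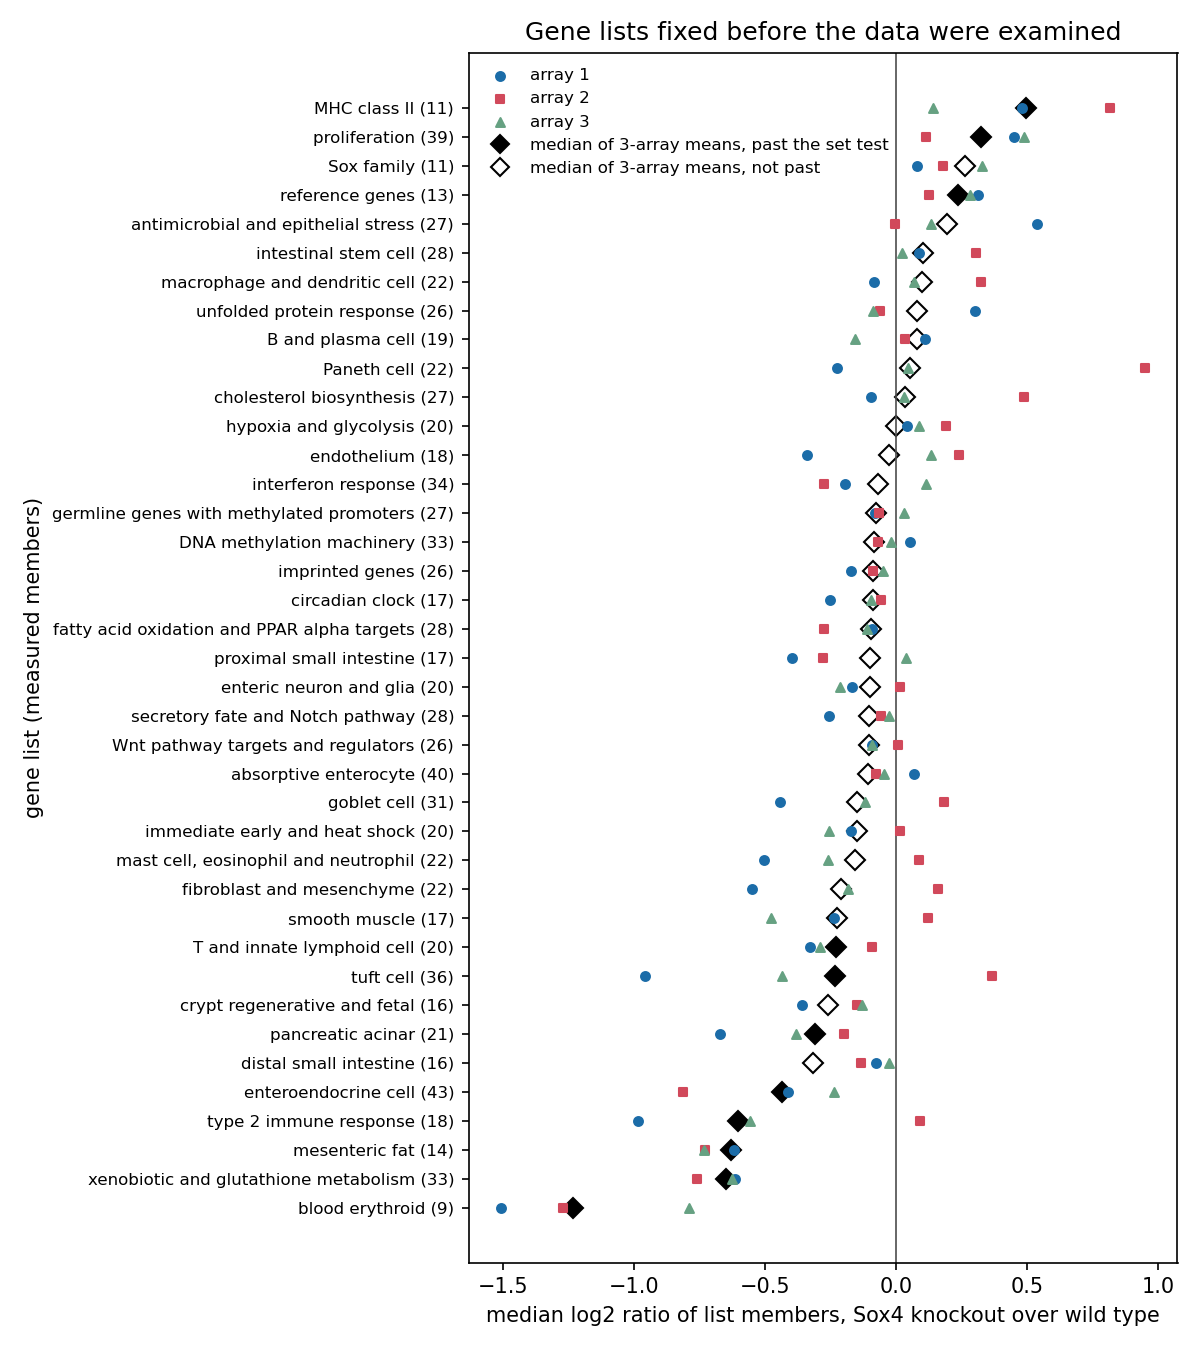
Median log2 ratio of Sox4 knockout over wild type (horizontal axis) for the 39 tested gene lists (vertical axis, with the number of measured members); coloured points are the medians on each array and diamonds the medians over genes of the 3-array mean, filled where camera with the preset correlation passed. The filled diamonds run from -1.23 for erythroid genes to 0.50 for MHC class II genes.

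The remaining tested lists did not pass, with adjusted p-values given from camera with the preset correlation. Members that passed only when adjusted over the list alone are described without a share for random lists, so they do not mark a list as changed. For DNA methylation machinery, the enzymes and binding proteins that write, remove and read this mark, none of 33 members passed limma's test in either count (median -0.08, adjusted p = 0.752). An unadjusted p under 0.05 was found for 8 of the 33, 4 in each direction, a smaller share than the 26.3% of all genes. Tet1, which oxidises methylcytosine, had -0.70 ± 0.20, Trim28 0.57 ± 0.10, Gadd45g -0.46 ± 0.14 and Apobec1 -0.46 ± 0.19. Imprinted genes (26 members, median -0.09, adjusted p = 0.438) had none past either count, with Cdkn1c at -0.77 ± 0.38, Phlda2 at -0.63 ± 0.42 and Peg3 at 0.38 ± 0.06. Germline genes with methylated promoters (27 members, median -0.07, mean -0.00, adjusted p = 0.986, with camera's direction upward) had 1 member, Asz1 (-0.73 ± 0.18), lower adjusted over the list alone.

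Among lists of crypt identity and fate, none had a member past the threshold over all genes. Adjusted over the list alone, stem cell genes (28 members, median 0.10, adjusted p = 0.0842) had 2 higher, Clca3b (0.95 ± 0.10) and Prom1 (0.70 ± 0.12), and Olfm4 had 0.61 ± 0.32. Lgr5 (-0.43 ± 0.34) and Slc14a1 (-0.44 ± 0.23), chosen after their values were seen, were below 0 on every array. Of the 28 members, 17 had a mean above 0 and 11 below. Sox family genes (11 members, median 0.26, adjusted p = 0.248) had 2 higher adjusted over the list alone, Sox13 (0.81 ± 0.32) and Sox12 (0.47 ± 0.14). Wnt pathway genes (26 members, median -0.10, adjusted p = 0.754) had 1 higher, Ccnd1 (0.78 ± 0.26), and 4 lower, among them Wif1 (-0.67 ± 0.18) and Rspo3 (-0.66 ± 0.20). Secretory fate and Notch genes (28 members, median -0.10, adjusted p = 0.520) had 1 higher, Lfng (0.97 ± 0.24), with Spdef at -0.72 ± 0.39. Regenerative and fetal crypt genes (16 members, median -0.26, adjusted p = 0.209) had none, with Krt7 at 0.48 ± 0.13 and Gja1 at -0.42 ± 0.12.

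Goblet cell genes (31 members, median -0.15, adjusted p = 0.517) had 2 higher and 3 lower adjusted over the list alone, among them the mucin gene Muc13 (2.82-fold higher, SD 0.56 on the log2 scale), Fcgbp (1.03 ± 0.47) and Scin (-1.15 ± 0.30), and none past over all genes. Paneth cell genes (22 members, median 0.05, mean -0.01, adjusted p = 0.438) had none in either count, with Defa5 at 0.69 ± 0.31, and array medians of -0.22, 0.95 and 0.05. Absorptive enterocyte genes (40 members, median -0.10, adjusted p = 0.986) had none past over all genes, and 1 higher and 4 lower adjusted over the list alone, among them Anpep (0.83 ± 0.15), Cyp3a11 (-1.05 ± 0.33) and Tm4sf4 (-1.56 ± 0.72), which passed over all genes without array 2 (adjusted p = 0.0360). The proximal list (17 members, median -0.10, adjusted p = 0.254) had none past over all genes, and 2 higher and 6 lower adjusted over the list alone, among them Gata4 (0.62 ± 0.12) and the glucose sensor gene Slc5a4a (-1.09 ± 0.34). In the distal list (16 members, median -0.32, adjusted p = 0.471), Pyy was the 1 member to fall in both counts.

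In the cholesterol biosynthesis list, which also holds genes of fatty acid synthesis (27 members, median 0.03, adjusted p = 0.248), Scd1 was the 1 gene to fall. Adjusted over the list alone, Scd1 was lower and 2 were higher, Fads1 (0.70 ± 0.18) and Fads2 (0.63 ± 0.10), and all of these encode fatty acid desaturases, not enzymes of cholesterol synthesis. Fatty acid oxidation genes (28 members, median -0.10, adjusted p = 0.124) had none past over all genes, and 1 higher and 4 lower adjusted over the list alone, with Cd36 at -1.09 ± 0.39 and Fgf21 at 0.75 ± 0.29. Hypoxia and glycolysis genes (20 members, median 0.00, adjusted p = 0.511) had 1 higher, Eno1 (0.82 ± 0.21), and 1 lower, Bnip3 (-0.70 ± 0.22), in the latter count. Circadian clock genes (17 members, median -0.09, adjusted p = 0.438) had none in either count, with Dbp at -0.46 ± 0.20 and Per3 at -0.44 ± 0.17. Unfolded protein response genes (26 members, median 0.08, adjusted p = 0.564) had 1 lower adjusted over the list alone, Trib3 (-0.83 ± 0.14). Immediate early and heat shock genes (20 members, median -0.15, adjusted p = 0.564) had none, with Fos at -0.70 ± 0.31.

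Antimicrobial and epithelial stress genes (27 members, median 0.20, adjusted p = 0.372) had none past either count. The bactericidal lectin gene Reg3g had a mean of 3.38 ± 2.44, with ratios of 4.74, 0.56 and 4.84 on arrays 1, 2 and 3, and passed without array 2 (4.79, adjusted p = 0.00386). Nos2 had 1.34 ± 1.07. Interferon response genes (34 members, median -0.07, adjusted p = 0.792) had 3 higher and 2 lower adjusted over the list alone, among them the immunoproteasome genes Psmb9 (0.59 ± 0.05) and Psmb8 (0.54 ± 0.02) and the effector gene Isg15 (-0.53 ± 0.16). B and plasma cell genes (19 members, median 0.08, adjusted p = 0.372) had 1 higher in that count, Blk (1.48 ± 0.48). Macrophage and dendritic cell genes (22 members, median 0.10, adjusted p = 0.277) had none, with Cd14 at 0.36 ± 0.22.

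The stromal lists had no member past the threshold over all genes. Smooth muscle (17 members, median -0.22, adjusted p = 0.277), fibroblast and mesenchyme (22 members, median -0.21, adjusted p = 0.299) and endothelium genes (18 members, median -0.02, adjusted p = 0.986, with camera's direction upward) also had none adjusted over the list alone. Pln had -0.72 ± 0.56, Postn -0.48 ± 0.07 and Flt4 0.53 ± 0.21. Enteric neuron and glia genes (20 members, median -0.10, adjusted p = 0.438) had 2 higher and 5 lower adjusted over the list alone, among them Snap25 (0.49 ± 0.09), S100b (-0.60 ± 0.12) and the neuropeptide gene Vip (-0.90 ± 0.51). Without array 2, smooth muscle, fibroblast and mast cell lists passed below 0 (adjusted p = 0.00176, 0.00361 and 7.3e-05), and goblet genes did too (adjusted p = 0.0213). The smooth muscle median was however -0.0035 without array 3 (adjusted p = 0.992), and the fibroblast median 0.03 without array 1 (adjusted p = 0.695). Without array 1, the stem cell, Paneth and cholesterol lists passed above 0 (adjusted p = 0.0285, 0.0211 and 0.00620) and fatty acid oxidation below 0 (adjusted p = 0.04995).

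Across genes, Pearson correlations between arrays were 0.43 for arrays 1 and 2, 0.57 for arrays 1 and 3 and 0.41 for arrays 2 and 3 (Spearman 0.46, 0.51 and 0.41). Genes are not independent replicates, and arrays that share dye orientation and possibly wild-type RNA correlate without any effect of genotype. The same sign on all 3 arrays was found for 50.6% of genes, where independent signs would give 25%.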

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

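Signal in features that the comparisons above leave out was tested after the gene results were seen. Among 31511 features unnamed here, limma with 1 value per feature, adjusted over all features, put 234 past an adjusted p of 0.05, 62 higher and 172 lower in the knockout. The features with a gene name gave 31 higher and 60 lower in the same fit. The unnamed feature farthest below 0 had a mean of -6.36 (arrays -6.55, -6.17 and -6.34) and the farthest above 0 a mean of 3.41 (arrays 3.31, 3.59 and 3.34). No explanation was tested for these features, whose genes are not used here.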

How the results depend on the processing

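None of the 11 lists past the threshold changed the sign of its median under the alternatives, but 13 of 39 tested lists, none of them past the threshold, did so when an array was left out (Paneth 0.05 to -0.13 without array 2, fibroblast -0.21 to 0.03 without array 1), and the cholesterol and hypoxia lists did under other settings. Sox4 did not pass under any of them, its mean running from -0.56 (without array 2) to -0.14 (without array 1), and to -0.95 for the feature with the smallest p. The 68 genes changed became 73 with median centring, 100 with quantile normalization, 50 with 1 median absolute log ratio per array, 71 with the median over features, 73 with robust moderation, 81 with 1 value per feature and 66 with accessions averaged first, an alternative chosen after seeing the data. Array weights (1.44, 0.69 and 1.01) gave 265 genes and 43 list members in place of 18. Leaving out genes with an exact 0 or an extreme value gave 170 genes, 67 of them shared, and 32 list members, with 589 fewer genes tested. For these 2 settings the cause was not tested. A minimum fold of 1.5 left 14 genes, and an adjusted p under 0.10 gave 2090, 992 higher and 1098 lower. An unadjusted p under 0.05 was nearly as frequent among the odorant, vomeronasal and taste receptor genes described below (25.0%) as among other genes (26.4%). For the 2090 genes a dye effect shared by the arrays cannot be separated from genotype, so they are not shown to be changed by it. Leaving out 1 array, with fewer residual degrees of freedom, gave 4 to 66 genes: 10 without array 1, 66 without array 2 and 4 without array 3, of which 9, 25 and 4 were among the 68. It gave 3 to 25 list members, and 12 of the 25 without array 2 were among the 18. The list shifts numbered 8 to 15. Of 11 list shifts, 6 passed whichever array was left out: proliferation and MHC class II above 0, and enteroendocrine, xenobiotic, erythroid and fat below 0. Camera with an estimated correlation called 0 lists (1 at an unadjusted p under 0.05), as it did for shifted lists of independent genes in simulated data. Fry, which does not compare a list with other genes, called 0 (7 unadjusted). In settings other than leaving out an array, 271 of 273 list values kept their side of the threshold, the exceptions being the T cell list (adjusted p = 0.0515 without exact zeros and extremes) and the mast cell list (adjusted p = 0.0306 with array weights). For single named genes, 1289 of 1334 such values kept it, 6 lost it and 39 gained it, and of 501 values with an array left out 448 kept it, 49 lost it and 4 gained it. The mean correlation between arrays stayed at 0.47. Without intensities the distance of a feature from background is unknown, so a feature near it cannot be told from an unchanged gene.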

Other observations

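Several further genes passed the threshold, named here after their values were seen. The water channel gene Aqp8 (-1.68 ± 0.20), the carbonic anhydrase gene Car1 (-1.54 ± 0.11), the peptide transporter gene Slc15a2 (-1.27 ± 0.20), the Wnt inhibitor gene Dkk4 (-1.60 ± 0.21) and the haemoglobin-binding protein gene Hp (-1.70 ± 0.37) fell. Both Car1 features were below 0, at means of -0.52 and -2.56. The glutathione peroxidase gene Gpx2 (1.19 ± 0.20), the carboxylesterase gene Ces2f (1.19 ± 0.06), the peptidoglycan recognition gene Pglyrp1 (1.26 ± 0.25) and the posterior patterning gene Hoxd13 (1.09 ± 0.08) rose. Gpx2 and Ces2f thus went up while 27 of 33 fixed genes of xenobiotic and glutathione metabolism were below 0 on all arrays.

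Genes of odorant, vomeronasal and bitter taste receptors, a class chosen after seeing the data because Olfr487 had risen, had a median of 0.12 over 1380 genes, against -0.04 over the other 19358. Olfr487 and the bitter taste receptor gene Tas2r143 (1.11 ± 0.12) passed. An unadjusted p under 0.05 was found for 25.0% of the receptor genes and 26.4% of the others, and the receptor genes correlated between arrays at 0.28, 0.31 and 0.25 (Pearson, across genes).

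In what follows, the tests of a more distal position, of an equal loss of enteroendocrine subtypes, of noise between spots and of wild-type RNA in both channels were chosen after the result was seen. The 68 genes past the threshold were set against the sign choices of the 3 arrays: 1 of 4 choices gave as many, the real one, and each of the others gave 0 by limma (235 to 489 genes at an unadjusted p under 0.05, against 5451). With 4 choices the share cannot lie under 0.05. Turning an array also cancels any ratio that the arrays share, whether from genotype, dye, sex or wild-type RNA. The counts therefore do not bear on genotype.

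The Y-linked genes Eif2s3y, Uty and Ssty2 were lower on all 3 arrays, as were 11 of 14 genes of the fat list and 6 of 9 of the erythroid list. A difference in sex between the knockout mice and the wild-type RNA is a candidate explanation for the Y-linked part: Xist was above and Eif2s3y below 0 on every array, values already seen when the test was set, while 5 X-linked genes known to escape inactivation had a median of 0.20, at the 91.5th percentile of random lists and short of the 95th set in advance, with Kdm5c (mean 0.70) above 0 and Eif2s3x (-0.24) and Ddx3x (-0.18) below 0 on every array, and Kdm6a (0.48) and Pbdc1 (0.20) of mixed sign. Sox4 loss limited to the epithelium would leave Y-linked transcripts of the other cells of the tissue. Eif2s3y at -7.44, -6.99 and -7.40 and Uty at -2.64, -4.09 and -2.42 on arrays 1, 2 and 3 argue against such loss as their source. Ssty2 and Kdm5d were also below 0 on every array. No separate test of this was run. A difference in sex would lie in the same contrast as genotype for every other gene too, on every array. More fat in the wild-type RNA is a candidate for the fat part, where 9 further adipocyte genes had a median of -0.39, 7 of them below 0, at the 0.25th percentile of random lists and so inside the 5th set in advance, but short of the other bound (-0.5). For the fat genes it cannot be told apart from an effect of Sox4 loss, because each array holds the same contrast, and the haemoglobin genes were not tested separately.

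The enteroendocrine hormone genes Nts, Gcg, Cck and Pyy fell. Islet RNA in the wild-type sample, which would carry insulin along with Gcg, is argued against by Ins2, whose lowest ratio was 0.56 (Ins1 was not measured). However, Iapp, made in islets and gut hormone cells and chosen after its value was seen, had -1.60 ± 1.03. The acinar list had a median of -0.31, and pancreatic RNA without islets was not tested. An equal loss of all enteroendocrine subtypes was set against Ghrl at 0.68 (95% interval 0.40 to 0.96), Sct at 0.04 ± 0.59 and Chgb at -0.00 ± 0.59. These genes were chosen after they were seen not to be lower, and Ghrl did not pass over all genes (limma adjusted p = 0.0658). The comparison therefore shows only that Ghrl did not fall, and does not decide the question for the subtypes. A more distal position of the wild-type segment was not settled by the distal list without Pyy. The median of that list was -0.26 (bootstrap 95% interval -0.46 to 0.25), with 7 of 15 members above 0. Slc10a2 had -0.51, and Fabp6 at 0.22 and Fgf15 at 0.11 were chosen after their values were seen. The proximal list did not settle it either (-0.10, -0.79 to 0.03). Such a position stays open, also because without intensities it is unknown whether the distal genes were above background. An effect of Sox4 loss on hormone cells stays open as well, untested here because no cells were counted.

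The medians of tuft cell and type 2 genes were below 0 on arrays 1 and 3 and not on array 2, where Reg3g also stood apart (0.56 against 4.74 and 4.84). The same arrangement was found on arrays 1, 2 and 3 for smooth muscle (-0.23, 0.12 and -0.48), fibroblast (-0.55, 0.16 and -0.18) and goblet genes (-0.44, 0.18 and -0.12). It was therefore not particular to tuft and type 2 genes. More noise between the spots of array 2 is argued against by its replicate features, whose median SD of 0.0654 was the lowest of the 3 (0.103 and 0.0807 on arrays 1 and 3), and wild-type RNA in both channels by Gcg at -5.37 on that array. That does not reach faults of RNA or labelling that all spots of a gene share, which stay open, as its weight (0.69 against 1.44 and 1.01) and its correlations (0.43 and 0.41 against 0.57) were the lowest. A difference in type 2 immune activity between the mice is a candidate explanation, and 6 genes of the mast cell list described above had medians of -3.73, -0.01 and -2.54 on arrays 1, 2 and 3, with Cma1 (-0.49, -0.05 and -0.41) and Tpsb2 (-0.42, 0.74 and 0.50) far from these on arrays 1 and 3, but the arrangement had been seen in Mcpt1, Mcpt2 and Il13, and lower values on array 1 in Retnlb, before that test, so it adds little and does not show the origin. Incomplete deletion in the mouse of array 2 and another wild-type mouse as its reference were not tested; the Sox4 mean of 0.18 there rests on feature 32792 (1.23, against -0.72 for feature 53932), and Nts (-6.86), Gcg and the enteroendocrine median (-0.81) lay farthest below 0 on that array.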
